A study of Homo sapiens with 2 samples.

How the data were processed

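RNA was profiled in 2 libraries of SK-ES-1, an established Ewing sarcoma cell line, with 1 library of slow-cycling cells and 1 library of non-slow-cycling cells. Per the labels' protocols, total RNA was isolated with a phenol-based reagent and sequencing libraries were made with a stranded mRNA kit that selects polyadenylated transcripts. The human genome build was hg38, per the submitters' processing notes. The aligner, the quantification tool, the gene annotation and the way the slow-cycling cells were isolated are not given in the sources used here.

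Each library came as 1 column of values with a gene symbol and an Entrez gene ID per line, called normalized per the file headers. The column headers use the abbreviations LRC and non-LRC, which the sources do not explain, where the labels name slow-cycling and non-slow-cycling cells. Each table was assigned to a group through the sample it was deposited for, and the direction of every ratio rests on that assignment. The deposited values were taken to be log2 values, from the numbers themselves: they held no negative value, reached 15.6 in the slow-cycling and 15.2 in the non-slow-cycling library, and, after 1 was subtracted from 2 raised to each value, summed to 983638 and 984120. Such sums lie close to those of TPM values with 1 added before the logarithm, but the scale was not stated, so levels are given here as per-million units, back-transformed from the deposited log2 values. The read depth of each library was unknown, because these values keep no read counts, and no counting interval was computed. An exact 0 in such a table can be a failed estimate. All 13 protein-coding genes of mitochondrial DNA, which every cell uses, were listed at 0 in both libraries, so a gene at 0 is described only as listed at 0.

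Each table had 53826 lines. Lines of 1 Entrez gene ID that differed only in a locus suffix, of which there were 174, were summed in per-million units, which left 53737 genes. Gene class and coordinates came from the RefSeq table of the GRCh38.p14 assembly, the patched form of the build the submitters name, in which 51252 gene IDs were matched and 2485 were not. A gene was tested when it had at least 1 per-million unit in at least 1 library, which 13444 genes had, 11833 of them protein-coding. The ratio of a gene is the difference of its log2(value + 1) in the slow-cycling minus the non-slow-cycling library. The pseudocount of 1 is the one inferred for the deposited values, and this scale understates the difference of low genes. No further scaling was applied, since the median log2 ratio of tested genes was 0.03.

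With 1 library per group no difference had a replicate check, and no p-value was computed. Genes at least 2-fold higher or lower were counted. For each of 40 gene lists, the tested members, those at least 1.5-fold higher or lower and the median log2 ratio were given. The percentile of that median was taken among 10000 random lists of the same size, matched on mean expression in 20 bins, and a list was said to stand apart when its median lay outside the 2.5th to 97.5th percentile. That percentile describes these 2 libraries. Its random lists are drawn gene by gene, while genes of a pathway can vary together, so it is not a p-value for the groups. The lists, drawn from general knowledge of the pathways, and all rules were fixed before the data were examined. They covered the cell cycle, stress, metabolism, signalling, targets of the Ewing sarcoma fusion protein EWSR1-FLI1 and markers of other cell types. The genes named are the 12 protein-coding genes with the highest and the 12 with the lowest log2 ratio, up to 4 members with the largest absolute ratio of each list that stood apart, and 29 genes fixed in advance. Any other named gene was chosen after its values were seen, and is said to be so. Some items that these rules name are not reported here.

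On simulated data made from the 13444 tested genes, the 2-fold count found 100% of the genes seeded at 3-fold and 100% of those seeded at 4-fold, while 1.15% of unchanged genes passed it. Only genes with a mean log2(value + 1) above 3 were seeded, and the shift was added to the ratio itself. Recovery of low genes was therefore not tested. The noise was set from the interquartile range of the real ratios in each expression bin, since there were no replicates to set it. Of simulated lists of 30 unchanged genes, 5% fell outside the middle 95% of random lists, and 99.5% of lists shifted by 0.2 on the log2 scale did. Noise was drawn independently for each gene, so lists whose members vary together were not simulated.

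The alternatives were a median log2 ratio set to 0, upper quartile scaling, no filter, 5 times the minimum level, a pseudocount of 0.1, other fold thresholds, protein-coding genes alone, list members held by 1 list only, and random lists not matched on expression. Added after seeing the data were genes above 0 in both libraries, genes at 4 per-million units or more in both, and ratios with the trends over GC content, transcript length and level removed, the first 2 of these properties from GENCODE 29 transcripts. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.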

Results

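Gene expression was compared between slow-cycling and non-slow-cycling SK-ES-1 cells, to ask which transcripts differ between the slowly dividing fraction of this Ewing sarcoma line and the rest. The design had 2 libraries, 1 per group, so every difference below is a difference between these 2 libraries with no replicate check. In the slow-cycling library 14606 table entries had a value above 0, and in the non-slow-cycling library 14197 did. The read depth behind them was unknown. Over the 13444 tested genes the log2 values of the libraries correlated across genes with a Pearson r of 0.987, genes not being independent replicates, and 93.2% of genes lay within 1.5-fold.

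The slow-cycling library had higher levels of immediate early genes, of hypoxia-response genes and of genes that EWSR1-FLI1 represses. The mixed list of cell cycle brakes and genes of non-dividing cells was higher as well. Its levels of S phase genes, ribosome biogenesis genes and nuclear genes of oxidative phosphorylation were lower. Genes of G2 and mitosis were also higher in the slow-cycling library, with a median log2 ratio of 0.23, equal at this rounding to that of the list of brakes. The genes that EWSR1-FLI1 activates did not stand apart. Of the 39 lists with at least 3 tested members, 15 had a median above the middle 95% of their random lists and 3 a median below it. For lists of unrelated genes, 1.95 lists would be outside by chance. Genes of a pathway can vary together, so that number does not measure chance for these lists.

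**Figure D1:**
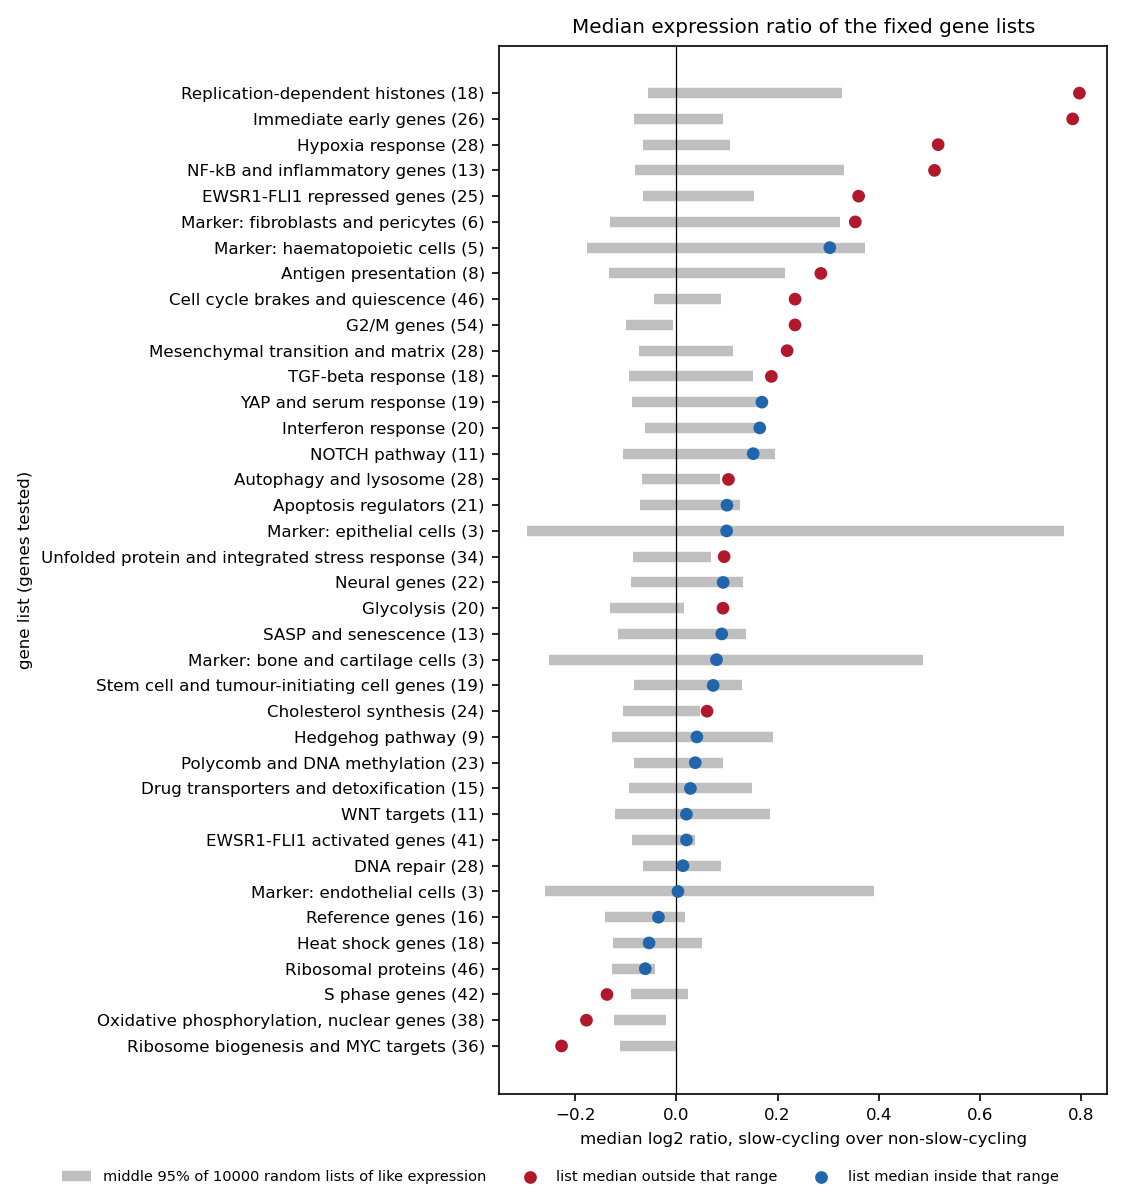
Median log2 ratio, slow-cycling over non-slow-cycling library, of the fixed gene lists reported here (points, with the number of genes tested in parentheses), over the middle 95% of 10000 random lists of like expression (grey bars). Red points lie outside that range: histones at 0.80 and immediate early genes at 0.78 are the 2 highest, and ribosome biogenesis genes at -0.23 the lowest.

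Of the 13444 tested genes, 255 were at least 2-fold higher in the slow-cycling library and 58 at least 2-fold lower. In the simulated data 1.15% of unchanged genes passed the 2-fold count, so part of these genes can be noise. Among 11833 protein-coding genes the counts were 151 higher and 12 lower, and among 884 long non-coding genes 36 and 18. Among only 353 small non-coding genes they were 56 and 27. The library kit selects polyadenylated transcripts, so the levels of small non-coding genes that lack a poly(A) tail are uncertain. Of the 255 higher genes, 107 were listed at 0 in the non-slow-cycling library, and of the 58 lower genes, 13 were listed at 0 in the slow-cycling library. With the filter and pseudocount used, every tested gene listed at 0 in 1 library is at least 2-fold apart by construction, and without these genes the counts were 148 higher and 45 lower. Genes at 4 per-million units or more in both libraries, a restriction added after seeing the data, gave 22 higher and 5 lower. The ratios moved with expression level: the median log2 ratio was 0.23 for genes with a mean of 1 to 2 per-million units and -0.06 for genes at 64 or more.

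EGR3, a zinc finger transcription factor of the immediate early class, was the highest of the 12 leading protein-coding genes that is neither a read-through model nor listed at 0 in the other library. It lies on chromosome 8 (22687659 to 22693480, GRCh38) and was at 12.8 per-million units in the slow-cycling and 1.80 in the non-slow-cycling library, a log2 ratio of 2.30. Its relative EGR4, on chromosome 2 (73290929 to 73293548), was at 2.97 and listed at 0. NLRP1, an inflammasome sensor on chromosome 17 (5501396 to 5584509), was at 13.4 and 2.72, a log2 ratio of 1.95. EEF1A2, a translation elongation factor of neurons and muscle on chromosome 20 (63488014 to 63499083), was at 38.7 and 9.32, and FXYD5, a regulator of the sodium pump on chromosome 19 (35154735 to 35169881), at 7.12 and 1.12, both with a log2 ratio of 1.94. TMEM59L was at 4.27 and 0.179, and C16orf45 at 3.31 and listed at 0. HYI was at 18.1 in the slow-cycling library and listed at 0 in the other. MBD3L4, at 11.6 and 1.97, belongs to a family of near-identical copies among which reads can be split, so its value is uncertain.

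The other 3 of the 12 were read-through models, annotated transcripts that run through neighbouring genes and overlap them. TGIF2-C20orf24 was at 39.2 and listed at 0, SYNJ2BP-COX16 at 17.9 and 0.484, and TMEM110-MUSTN1 at 5.16 and listed at 0. COX16, which lies within the SYNJ2BP-COX16 model on chromosome 14 (70325081 to 70359683), was among the 12 lowest genes, at 30.2 and 62.1 with a log2 ratio of -1.01. Reads of overlapping models can be divided between them in more than 1 way.

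Among the 12 lowest protein-coding genes were 2 receptors. LPAR3, a lysophosphatidic acid receptor on chromosome 1 (84811602 to 84893206), was at 0.114 per-million units in the slow-cycling and 1.77 in the non-slow-cycling library, and EPHB1, an ephrin receptor on chromosome 3 (134795260 to 135260467), at 1.07 and 3.91, a log2 ratio of -1.25. TMEM88 was at 1.27 and 4.38, PCP4 at 0.210 and 1.86, the growth factor NRG4 at 0.0582 and 1.31, C6orf226 at 2.33 and 5.89 and the protocadherin PCDHGA6, which shares exons with its neighbours, at 1.29 and 3.65. Besides COX16, the other 4 were histone genes of the cluster on chromosome 6. HIST1H4K was at 2.29 and 5.84, HIST1H3J at 0.356 and 1.96, and HIST1H2AL and HIST1H3B were listed at 0 in the slow-cycling library and at 1.27 and 1.16 in the other.

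Genes of DNA synthesis were lower in the slow-cycling library. Of 42 S phase genes, 39 had a ratio below 0, with a median log2 ratio of -0.14, which 1 of 10000 random lists reached (middle 95% of random medians, -0.09 to 0.02), although no member differed by 1.5-fold. The DNA polymerase clamp PCNA was at 457 per-million units against 538 in the non-slow-cycling library, a log2 ratio of -0.24. The replicative helicase subunits MCM5, at 174 and 223, and MCM6, at 107 and 138, had log2 ratios of -0.36 and -0.35. Cyclin E2, CCNE2, was at 32.4 and 42.0, and CDCA7 at 69.9 and 98.9, the largest difference of the list at -0.49.

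Genes of G2 and mitosis were higher. Of 54 G2/M genes, 50 had a ratio above 0, with a median log2 ratio of 0.23, which none of 10000 random lists reached (-0.10 to -0.01), again with no member at 1.5-fold. The mitotic spindle gene CKAP2L was at 33.6 and 22.4, the kinase NEK2 at 53.7 and 38.1, the centromere histone chaperone HJURP at 69.4 and 52.4, and the ubiquitin-conjugating enzyme UBE2C at 334 and 254. Topoisomerase TOP2A had a log2 ratio of 0.34, the proliferation marker MKI67 0.18, and cyclin B1, CCNB1, 0.19. The difference of the 2 medians, G2/M minus S phase, was 0.37.

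Histone genes went both ways. Of 18 tested members of the histone list, 11 were at least 1.5-fold higher and 3 at least 1.5-fold lower. Their median log2 ratio was 0.80, above all 10000 random lists (-0.06 to 0.33). HIST1H2AC was at 38.2 and 16.1, HIST1H2AG at 3.66 and 0.843, HIST1H2BG at 4.17 and 1.14, and HIST1H4H at 2.32 and 0.520. These genes share near-identical copies, and most of their transcripts lack the poly(A) tail on which the library kit selects, so their levels are uncertain. Without HIST1H3B, the member listed at 0, the median was 0.92. The list does not hold every histone gene, so its median describes its members alone. It leaves out HIST1H2AL, at -1.18 on the log2 scale and among the lowest genes named above. It also leaves out HIST1H2BF, at 1.48 and chosen after its values were seen.

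Of 46 cell cycle brakes and genes of non-dividing cells, 37 had a ratio above 0 and 9 were at least 1.5-fold higher, with none at least 1.5-fold lower. Their median log2 ratio of 0.23 was above all 10000 random lists (-0.04 to 0.09). The CDK inhibitor CDKN1C was at 6.29 and 3.24, with a log2 ratio of 0.78, and CDKN1A at 1.67 and listed at 0. The transcription factor KLF2 was at 11.2 and 3.33, the growth factor TGFB2 at 2.62 and 0.915, and TXNIP, a thioredoxin inhibitor, at 123 and 81.3, a log2 ratio of 0.59. The CDK inhibitor CDKN1B (0.06), RBL2 (-0.06) and the cyclin CCND1 (0.02) lay within 0.1 of 0 on the log2 scale. The list is mixed, since it also holds cyclins such as CCND1 and immediate early genes such as KLF2. Over the 32 members held by no other list its median was 0.23.

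Immediate early genes, which cells transcribe within an hour of stimulation or handling, were higher nearly throughout. Of 26 tested, 25 had a ratio above 0 and 18 were at least 1.5-fold higher, and the median log2 ratio of 0.78 was above all 10000 random lists (-0.08 to 0.09). FOSB was at 99.8 and 29.9, a log2 ratio of 1.71, and ATF3 at 20.9 and 5.70, also 1.71. MYC, a member of the list, was at 375 and 381. The abundant members EGR1, at 810 and 521, and JUN, at 411 and 212, were chosen after their values were seen.

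Hypoxia-response genes, targets of the HIF transcription factors, were higher in 27 of 28 cases, 10 of them by at least 1.5-fold, with a median log2 ratio of 0.52 above all 10000 random lists (-0.07 to 0.11). Carbonic anhydrase CA9 was at 3.28 and 0.660, the collagen prolyl hydroxylase P4HA2 had a log2 ratio of 1.22, the glucose transporter SLC2A3 was at 39.4 and 20.9, and BHLHE40 at 2.02 and listed at 0. VEGFA, a classical target, had a log2 ratio of 0.14. Of 20 glycolysis genes, 14 were above 0 and 2 at least 1.5-fold higher, with a median of 0.09 (random lists, -0.13 to 0.02), led by ALDOC at 114 and 64.1. The lactate exporter SLC16A3 had a log2 ratio of 0.80, HK1 was at 46.5 and 34.5, SLC2A1 at 82.4 and 64.4, and GAPDH had a log2 ratio of -0.13. The glycolysis median was 0.06 with the median of all genes set to 0, 0.05 over members held by no other list, and 0.17 after removal of the GC, length and level trends, which were taken out after seeing the data. Among random lists not matched on expression it no longer stood apart, at percentile 84.4.

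Growth and respiration genes were lower by small amounts in nearly every member. Of 36 ribosome biogenesis genes and MYC targets, 35 had a ratio below 0, with a median log2 ratio of -0.23, below all 10000 random lists (-0.11 to 0.00), led by NME1 at 376 and 504, MRTO4 at 143 and 183, RCL1 at 36.3 and 46.3 and BOP1 at 121 and 151. Of 38 nuclear genes of oxidative phosphorylation, 36 were below 0, with a median of -0.18, below all 10000 random lists (-0.12 to -0.02). ATP synthase subunit ATP5G1 was at 190 and 252, NDUFA6 at 120 and 147, NDUFA9 at 119 and 144, and COX8A at 423 and 513. No member of either list differed by 1.5-fold, and the oxidative phosphorylation median was -0.10 after removal of the trends. The 46 ribosomal protein genes had a median of -0.06 at percentile 85.0 of random lists of like expression, and of 0.02 after removal of the trends.

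The genes that EWSR1-FLI1, the fusion transcription factor that drives Ewing sarcoma, is known to activate showed no common direction. Of 41 tested, 22 had a ratio above 0 and 19 below, and the median log2 ratio was 0.02, at percentile 92.6, and turned to -0.01 with the median of all genes set to 0. NR0B1 was at 95.3 and 118, a log2 ratio of -0.30, NKX2-2 at 99.3 and 111 (-0.16), CD99 at 213 and 245 (-0.20), and CCND1 at 1081 and 1066. EWSR1 was at 254 and 284 and FLI1 at 34.5 and 36.6. Such levels per gene do not separate the fusion transcript from transcripts of the unfused genes.

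The genes known to be repressed by the fusion were higher in 22 of 25 cases, 10 of them by at least 1.5-fold, with a median log2 ratio of 0.36 above all 10000 random lists (-0.07 to 0.15). Only 8 of the 25 are held by no other list, and their median was 0.38. CYR61 and CTGF also belong to the YAP and serum response list. CYR61 was at 175 and 85.3, CTGF at 4.37 and 1.60, fibrillin FBN1 at 1.77 and 0.180, and IGFBP3 at 12.3 and 7.30. The collagen cross-linking enzyme LOX had a log2 ratio of 0.65. Mesenchymal and matrix genes were above 0 in 24 of 28 cases, 7 of them by at least 1.5-fold, with a median of 0.22, reached by 1 random list of 10000 (-0.07 to 0.11), and of 0.19 without COL6A1. The collagen COL6A2 was at 6.43 and 1.74, SNAI2 at 2.10 and 0.350, COL1A1 at 3.19 and 1.15, and COL6A1 at 2.33 and listed at 0. The markers of fibroblasts and pericytes moved with both lists: all 6 tested were above 0, with a median of 0.35 at percentile 98.6, and 4 of the 6 also belong to the list of repressed genes. Among these markers FAP was at 3.67 and 1.74, PDGFRB at 7.77 and 5.84, and DCN at 15.1 and 11.7. Their median was inside the random range with no filter and at 5 times the minimum level, at 0.26 and 0.24.

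**Figure D2:**
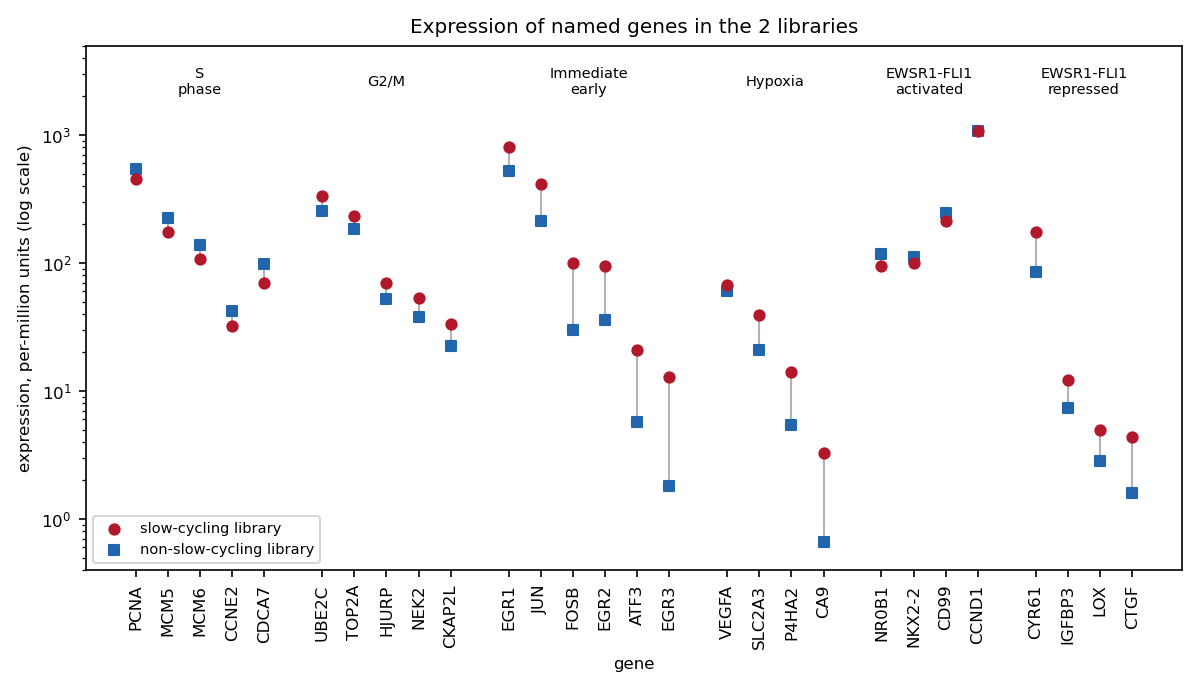
Expression of a choice of named genes of 6 lists in per-million units (log axis), with red circles for the slow-cycling and blue squares for the non-slow-cycling library, 1 library each, joined by a line per gene. Of the genes drawn, EGR3 has the widest gap, at 12.8 and 1.80, while the S phase gene PCNA is lower in the slow-cycling library, at 457 and 538. EGR1, EGR2 and JUN were chosen after their values were seen.

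The tested inflammatory genes were higher, though mostly at low levels. Of 31 NF-kB and inflammatory genes, 15 were listed at 0 in both libraries and 13 were tested. Of these 13, 12 had a ratio above 0 and 5 were at least 1.5-fold higher. Of the 5, 3 were listed at 0 in the non-slow-cycling library: PTGS2, at 1.88 in the slow-cycling library, CCL20, at 1.06, and CXCL3, at 1.04. The median was 0.51 with these 3 and 0.40 without them, and 4 of 10000 random lists reached the former. NFKB2 was at 14.3 and 7.86. Of 22 antigen presentation genes, 13 were listed at 0 in both libraries. Of the 8 tested, 7 were above 0, with a median of 0.29 at percentile 99.6. HLA-C was at 21.2 and 10.2, HLA-B at 6.62 and 2.92 and HLA-E at 42.2 and 29.2, genes alike enough to share reads, while the proteasome subunit PSMB10 was lower at 4.66 and 8.20. The list was inside its random range, at 0.21, with no filter on low values. Of 18 TGF-beta response genes, 13 had a ratio above 0 and 5 a ratio below 0, with a median of 0.19 at percentile 99.4. At least 1.5-fold higher were 5, among them JUNB, also on the immediate early list, at 192 and 106. Over the 12 members held by no other list the median was 0.15, at percentile 98.3.

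Of 34 genes of the unfolded protein and integrated stress responses, 9 were at least 1.5-fold higher and none lower by as much, with a median of 0.09 at percentile 99.5. The stress transcription factor DDIT3 was at 44.7 and 18.6, the lipoprotein receptor VLDLR at 6.80 and 2.72, and the pseudokinase TRIB3 at 10.5 and 4.79. The median was 0.06 with the median of all genes set to 0, and inside the random range, at 0.02, over members held by no other list. Autophagy and lysosome genes had a median of 0.10 over 28 members at percentile 98.9, led by MAP1LC3B at 45.6 and 31.2, ATG9B at 5.27 and 3.48, GABARAPL1 at 151 and 110 and ATP6V1A at 33.6 and 25.3. Cholesterol synthesis genes had a median of 0.06 over 24 members at percentile 98.9, led by STARD4 at 2.65 and 0.725, MVD at 37.8 and 24.8 and INSIG1 at 73.4 and 58.9. The latter median was 0.03 with the median of all genes set to 0, and both lists fell inside their random ranges after removal of the trends. Among random lists not matched on expression, the stress response, autophagy and cholesterol lists no longer stood apart, at percentiles 91.5, 92.1 and 69.5.

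Stem cell and tumour-initiating cell genes did not stand apart, with a median of 0.07 over 19 members at percentile 80.9. PROM1, the surface protein CD133, was at 5.25 and 2.63, a log2 ratio of 0.78, whereas SOX2 (-0.02), LGR5 (-0.13) and ALDH1A1 (-0.04) were at or slightly below the level of the non-slow-cycling library. CD44 and CXCR4 were listed at 0 in both libraries. Medians inside the random range were also found for drug transporters (0.03 over 15 members), neural genes (0.09 over 22), interferon response genes (0.16 over 20, percentile 96.8), WNT targets (0.02 over 11), NOTCH genes (0.15 over 11), Hedgehog genes (0.04 over 9) and YAP and serum response genes (0.17 over 19, percentile 97.1). The same held for apoptosis regulators (0.10 over 21), senescence genes (0.09 over 13), DNA repair genes (0.01 over 28) and Polycomb and DNA methylation genes (0.04 over 23). Heat shock genes had a median of -0.05 over 18 members at percentile 40.3, with a mean of opposite sign, 0.04. Of these medians, those of drug transporters, WNT targets and DNA repair genes changed sign when the median of all genes was set to 0. That of apoptosis regulators was -0.02 over members held by no other list and -0.01 after removal of the trends, so none of these 4 lists has a direction. After removal of the trends the median was 0.06 for interferon response genes, 0.10 for YAP and serum response genes, 0.02 for stem cell genes, 0.05 for neural genes, 0.09 for NOTCH genes, 0.01 for Hedgehog genes and for drug transporters, and 0.00389 for Polycomb and DNA methylation genes.

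Of markers of other cell types, those of haematopoietic cells were above 0 in 5 of 5 tested, with a median of 0.30 at percentile 94.2 and 11 of the 18 markers listed at 0 in both libraries. Endothelial, epithelial, and bone and cartilage markers had 3 tested members each and medians of 0.00, 0.10 and 0.08, all inside their random ranges, and each changed sign after removal of the trends. The 16 reference genes had a median of -0.04, or 0.01 after removal of the trends, with ACTB at -0.07 on the log2 scale. Several genes belong to more than 1 list, CDKN1A, BHLHE40, ATF3 and COL1A1 among them, so the lists are not independent of each other.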

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

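No list median changed sign among the lists that stood apart, and of those 18 lists 12 stood apart in the same direction under all 9 list alternatives: S phase, G2/M, histones, cell cycle brakes, hypoxia, oxidative phosphorylation, EWSR1-FLI1 repressed, mesenchymal, NF-kB, TGF-beta, immediate early and ribosome biogenesis genes. Chosen after seeing the data were the alternatives of genes above 0 in both libraries, genes at 4 or more in both, and trends removed. The counts of genes depended on low values and on the threshold by construction: with 255 higher and 58 lower genes as reported, there were 60 and 11 at 5 times the minimum level, 488 and 127 with a pseudocount of 0.1, 723 and 189 at 1.5-fold, 21 and 2 at 4-fold, 151 and 12 among protein-coding genes, 22 and 5 at 4 or more in both libraries, and 148 and 45 among genes above 0 in both. Random lists not matched on expression ended the calls of glycolysis (0.0922), unfolded protein response (0.0945), autophagy (0.10) and cholesterol synthesis (0.0607), and added interferon response (0.16), YAP and serum response (0.17), ribosomal proteins (-0.0614) and haematopoietic markers (0.30). These changed in their random lists alone, since the medians are those reported. With no filter, antigen presentation (0.21) and fibroblast markers (0.26) no longer stood apart and YAP and serum response (0.19) did, as it also did with a pseudocount of 0.1 (0.19). Fibroblast markers at 5 times the minimum (0.24), the unfolded protein list without members of other lists (0.0201), and autophagy (0.0659) and cholesterol synthesis (0.0646) with trends removed were inside their random ranges. Fewer members enter the first 2 of these, and the cause was not tested for the others. The 153 alternative values of the 12 highest, the 12 lowest and the tested genes fixed in advance stayed on their side of 2-fold. Other named list members were not run under these alternatives. Scalings and intervals that need counts or FPKM values were not run, because the values were read as log2 values on a scale like that of TPM. The log2 ratios of low genes spread most: their SD was 0.591 for genes with a mean of 1 to 2 per-million units and 0.178 at 64 or more. Read depth was unknown, and its part in this spread was not tested.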

Other observations

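The lists and genes of this paragraph and the next were picked after their values were seen, as were the tests below on members near the floor, on handling and on read-through models. The removal of trends was added after seeing the data but before its own result. The stress response list was divided by branch, and the difference between the branches was not tested. Of 18 genes of the ATF4 branch, the amino acid and integrated stress response, 8 were at least 1.5-fold higher in the slow-cycling library, with a median log2 ratio of 0.44. That median includes genes held by other lists, such as ATF3 and SESN2, and no median without them is given here. Of 16 chaperones and folding genes of the endoplasmic reticulum, 1 was at least 1.5-fold higher, with a median of -0.04. ATF4 itself was at 522 and 514 per-million units and the chaperone HSPA5 at 328 and 324, while PPP1R15A, a phosphatase subunit that reverses the ATF4-inducing signal, was at 133 and 70.3. The amino acid transporter subunits SLC7A5, at 181 and 66.6, and SLC3A2, at 158 and 103, were higher with log2 ratios of 1.42 and 0.61. The zinc-binding metallothioneins, a family of like sequence that may share reads, were higher in 4 of 4 genes, with MT1F at 14.7 and 5.25 and MT1G at 3.65 and 0.571.

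Of 78 nuclear genes of the mitochondrial ribosome, 77 had a ratio below 0, with a median of -0.19, and MRPL12 was at 189 and 263. The MTRNR2L genes, nuclear copies of the mitochondrial ribosomal RNA, were higher in 7 of 7 cases, with a median of 0.61, and MTRNR2L2 was at 11096 and 7275. These copies are alike enough to share reads, so the 7 are not separate cases. Together with MIR6723, at 49634 and 38465, and MIR4461, at 24677 and 19411, they made up 9.47% of the slow-cycling and 7.14% of the non-slow-cycling library. The genes of mitochondrial DNA were listed at 0 in both libraries, so these entries were not separated from mitochondrial transcripts of like sequence. A larger share of these transcripts shifts all other genes of the slow-cycling library by -0.04 on the log2 scale, a smaller shift than the medians of the lists that were lower.

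Immediate early genes were higher in the slow-cycling library by a median log2 ratio of 0.78. The median was 0.71 after the trends with GC content, transcript length and level were removed, above all random lists, which argues against those trends as the whole cause. A few members near the floor were not the source either, as the 21 members at 4 per-million units or more in both libraries had a median of 0.75. Different handling of the cell fractions before lysis stays open: the heat shock list, which a general handling stress might raise, had a median of -0.0538 inside its random range, but immediate early genes can respond to handling alone, and the sources give no handling step. The slow-cycling state and handling cannot be told apart with 1 library per group.

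S phase genes were lower and G2/M genes higher, with a difference of medians of 0.37. Removing the GC, length and level trends left it at 0.40, against -0.06 to 0.06 for the middle 95% of random list pairs, which argues against those trends. The share of cells in each phase was not measured here, so no biological explanation was tested. A difference between the 2 libraries that is not due to the cell fraction stays open.

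Read-through models led the genes that were higher in the slow-cycling library: of 97 tested models, 6 were at least 2-fold higher, 5 of which were listed at 0 in the non-slow-cycling library, and 0 at least 2-fold lower. The component genes of each of the 6 were lower as a sum, and their loss offset 30.7% to 185% of the gain of the model, with a median of 80.0%. It was 128% for TGIF2-C20orf24 and 185% for SYNJ2BP-COX16, but 38.9% for IPO11-LRRC70 and 30.7% for TMEM110-MUSTN1, whose second partners LRRC70 and MUSTN1 were themselves higher. If the units are scaled by transcript length, as TPM values are, reads moved between models of unlike length change in value. The percentages are therefore not shares of moved reads. The median log2 ratio of the summed components was -0.39, below all 10000 random sets of 6 from the other 91 models (-0.20 to 0.18). The values are consistent with reads divided differently between overlapping models for part of this pattern, and a gain of some models beyond that stays open, with no biological explanation tested.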
